A study of Mus musculus with 17 samples.

How the data were processed

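Single bone marrow-derived macrophages were sorted from cultures of C57BL/6 mice into plates for SPID-seq, a plate-based 3' single-cell RNA method, per the labels' protocols. Cultures were grown with human M-CSF, the medium was renewed on day 2, murine cytokines were added on day 6 and cells were collected 24 h later. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.15.0.4 and the genome build was mm10; the aligner and the counting tool are not given in the sources used here. The deposited tables hold whole-number counts per gene and well, which the authors did not normalize as far as the values show. They are read here as UMIs from the plate method; that duplicates were collapsed is not stated directly, which is a limit on every interval from counting. A deposited table of wells gives the plate, the number of cells sorted into each well and the authors' embedding coordinates, a score with no fixed range, used here only as present or absent. It gave no cell classes that could be used, so no cell types were named. Coordinates are from a gene annotation of build mm10, in which 91.56% of the 52542 gene symbols were found. The 92 spike-in entries held 0 counts and were left out.

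The 6 groups are M-CSF alone and 5 cytokines, taken from the treatment label with its replicate number. IL-10 replicate 1 was not used here. A plate was the replicate: the counts of its 6460 wells with a cell over the 17 plates were summed per plate, and the 68 empty wells were left out. Before the data were examined, the tests, the 33 gene lists (8 of them markers of other cell types), the rule for naming genes and most alternatives were fixed. Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, robust quasi-likelihood fit, 1 mean per group over all 17 plates, 11 residual degrees of freedom before moderation). The test covered 7098 genes, with Benjamini-Hochberg adjustment and a threshold of 0.05. The biological coefficient of variation was 16.7%. The 28 lists with at least 5 tested members were tested with limma 3.58.1 (voom and camera) at a preset correlation of 0.01, again with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the lists of a contrast. Members of a list were also adjusted over the list alone. The lists overlap in part: they have 754 entries for 685 genes. Of the 32 tumour-associated macrophage genes 27 are also in another list, so results of this list are not independent of the others. Of the 11 osteoclast markers 3 are in another list and 5 were over the floor of 3 UMIs in M-CSF plates; of the 17 lymphocyte markers 0 are in another list and 2 were over that floor (Ebf1 and Ighm).

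Genes were named by 3 rules. Per contrast, these were the 8 largest rises and the 8 largest falls among genes past the threshold with at least 20 CPM in the higher group and plates of the groups that did not overlap. Per list, they were up to 4 members with the smallest p, and Zeb2 was named in each contrast. The text gives part of these, and some genes that the rules name are not reported here. A fold against a group at 0 UMIs was computed against 3 UMIs over the group, and against 1 to 3 UMIs a ratio of counts is given with its exact 95% counting interval. For shares of cells, each cell was thinned to 1000 UMIs and shallower cells were left out, since the groups differ in depth. Median UMIs per cell were 571.5 with M-CSF alone, 524 with TGF-beta, 687 with IL-10, 704.8 with IL-13, 926 with IFN-gamma and 1169 with IL-4. Shares were compared between plates by two-sided exact permutation tests, in which 3 plates against 3, or 2 against 3, cannot go below 0.1. No doublet caller was run, as each well received 1 sorted cell, and wells over 5 times their plate's median UMIs were left out in an alternative. Replicates of a group differed by more than sampling noise, so no plates were merged. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for counts per cell and plots.

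The steps were tested on simulated counts drawn from the mean levels of M-CSF plates, each plate's total and the fitted dispersions. The rates hold under that model only. The shares recovered count only changed genes that passed the filter on low counts in the simulation, such as 37 of 87 for IL-4 at 2-fold. Of genes changed 2-fold, 42.5% were recovered for IL-4, 29.4% for IL-13, 27.1% for IL-10, 27.8% for TGF-beta, 38.4% for IFN-gamma and 32.2% for IL-4 against IL-13. Of genes changed 4-fold the shares were 85.9%, 84.9%, 79.1%, 82.2%, 86.5% and 88.0%. False calls made up 3.54% to 7.48% of calls, and 0 had the wrong sign. Alternatives were RLE scaling, no filter on low counts, DESeq2 1.42.0, a replicate block and a fit of the compared plates alone. Others were wells of 500 UMIs or more, cells of 1000 UMIs or more, thinned plates, thinned cells, no cycling cells and each plate left out in turn. After the data were seen, 4 more were added: embedded cells, no wells over 5 times the median, no neutrophil-rich cells and, for marker lists of other cell types, counts and sums without the member with most UMIs.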

Results

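The data are 3' single-cell RNA libraries of mouse bone marrow-derived macrophages, which are grown from marrow of 8-week-old C57BL/6 mice in macrophage colony-stimulating factor (M-CSF). On day 6 the cultures received IL-4, IL-13, IL-10, TGF-beta or IFN-gamma, or no cytokine besides M-CSF. After 24 h single cells were sorted into multi-well plates. The series title places the work in the study of ZEB2, a zinc-finger transcription factor, in tumour-associated macrophages. The comparisons ask how each cytokine changed Zeb2 and the macrophage programs around it. The 17 plates used here comprised 3 each for M-CSF alone, IL-4, IL-13, TGF-beta and IFN-gamma, and 2 for IL-10 (replicates 2 and 3). They held 6460 wells with a cell and 68 wells sorted empty, with 6514968 unique molecular identifiers (UMIs) in the wells with a cell. The plate totals ran from 217364 UMIs (TGF-beta replicate 3) to 642790 (IL-4 replicate 1), and the median cell had 716.5 UMIs. The mean plate total was 297331 ± 68651 UMIs with M-CSF alone, 252705 ± 53563 with TGF-beta, 365940 ± 75320 with IL-13, 460747 ± 90572 with IFN-gamma and 578332 ± 60388 with IL-4 (SD, n = 3), and 324900 ± 46219 with IL-10 (SD, n = 2). Levels below are in CPM, UMIs scaled to one common plate total with TMM factors, as mean ± SD over the plates of a group with these n, and a ± on a log2 fold change is its standard error. The labels do not say whether the plates of a group came from separate cultures or mice, so the p-values measure the spread between these plates, which may be technical. Plate labels are numbered group by group, and those of the IFN-gamma plates lie apart from the others. An effect of plate order or processing therefore cannot be told apart from that of a cytokine. A fold against a group with 0 UMIs is a lower bound against 3 UMIs over the group, and such bounds and the intervals on ratios of counts cover counting error only.

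Zeb2 (chromosome 2, 44983632 to 45117395, minus strand, mm10) was measured in every plate. It stood at 279 ± 38.5 CPM with M-CSF alone, 277 ± 31.7 with IL-4 and 212 ± 36.2 with IL-13. It stood at 306 ± 82.8 with IL-10, 301 ± 89.0 with TGF-beta and 182 ± 47.0 with IFN-gamma. Zeb2 fell with IFN-gamma, by 0.61 ± 0.20 on the log2 scale (95% interval −1.01 to −0.21), with an adjusted p of 0.0227 over all genes and 0.0159 over the 5 cytokines (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). In the same edgeR quasi-likelihood test the other contrasts did not pass: the log2 difference was −0.02 (−0.41 to 0.36; Benjamini-Hochberg adjusted p = 0.953) with IL-4, −0.40 (−0.80 to 0.01; adjusted p = 0.262) with IL-13, 0.13 (−0.31 to 0.57; adjusted p = 0.953) with IL-10 and 0.12 (−0.29 to 0.53; adjusted p = 0.821) with TGF-beta. Between IL-4 and IL-13 plates Zeb2 differed by 0.37 (−0.01 to 0.76), which did not pass either (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.254). The IFN-gamma call ended without M-CSF replicate 1 (−0.51, adjusted p = 0.133), without M-CSF replicate 2 (−0.62, adjusted p = 0.0613) and without IFN-gamma replicate 2 (−0.43, adjusted p = 0.188), each by edgeR quasi-likelihood with Benjamini-Hochberg adjustment. It also ended with no filter on low counts (−0.57, edgeR adjusted p = 0.0539), in cells of 1000 UMIs or more (−0.52, edgeR adjusted p = 0.204) and in DESeq2 (−0.61, adjusted p = 0.0717).

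**Figure D1:**
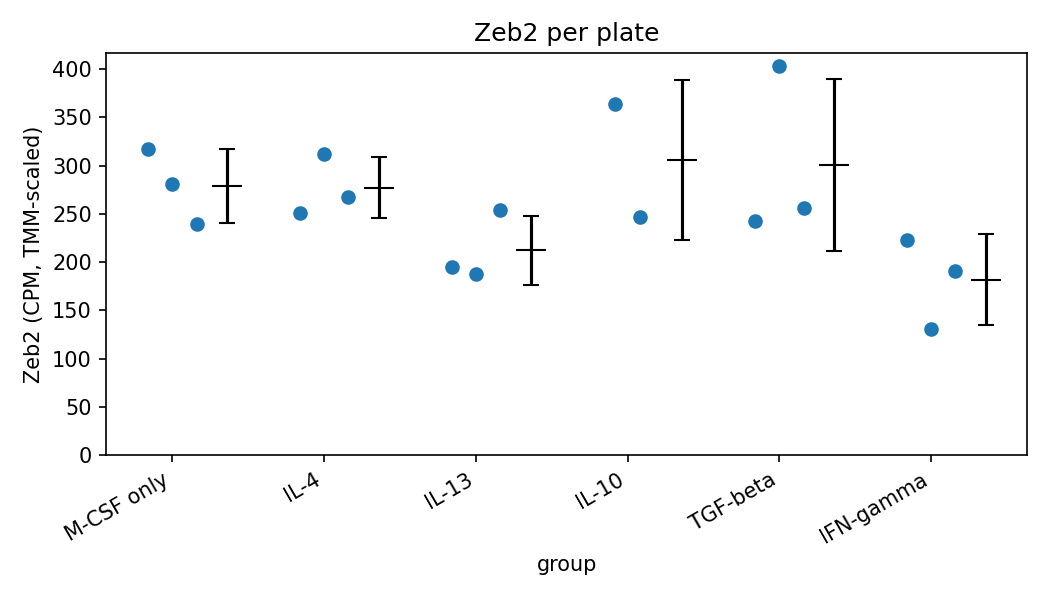
Zeb2 in CPM after TMM scaling on the vertical axis, for each plate (blue points) of the 6 groups on the horizontal axis; the black bar and whiskers are the group's mean and SD. The IFN-gamma plates average 182 CPM and the M-CSF plates 279 CPM.

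IL-4, a cytokine of type 2 immunity that drives alternative macrophage activation, switched on a set of genes that M-CSF plates lacked and lowered complement, microglia-type and interferon-stimulated genes. Arg1 (chromosome 10, 24915221 to 24927484, minus strand, mm10), which encodes arginase 1, reached 524 ± 113 CPM with IL-4 and had 0 UMIs with M-CSF alone, at least 149-fold higher. Apoe (chromosome 7, 19696109 to 19699188, minus strand, mm10), which encodes apolipoprotein E, went the other way, from 18391 ± 2862 to 1518 ± 139 CPM. In all 789 genes rose and 841 fell (533 and 611 of them by 2-fold or more) among the 7098 genes tested. Groups did not overlap for 37.8% of the genes, where chance gives 10%. Among other genes at 0 UMIs with M-CSF alone were Rnase2a (a ribonuclease of the eosinophil-associated family, 308 ± 81.1 CPM, at least 87.6-fold), Rbp4 (a retinol carrier, 140 ± 55.1 CPM, at least 39.7-fold), Serpinb9b (a protease inhibitor, 80.3 ± 6.2 CPM, at least 22.8-fold) and Lat (an adaptor of lymphocyte receptor signalling, 74.0 ± 7.69 CPM, at least 21.0-fold). Chil3, which encodes the secreted lectin Ym1, was at 466 ± 244 CPM against 2 UMIs in M-CSF plates, a ratio of 194 (counting interval 53.6 to 1607). Genes at 0 UMIs with IL-4 were Gpr34 (a lysophosphatidylserine receptor of microglia, 107 ± 25.8 CPM with M-CSF alone, at least 60.9-fold lower), Gm13710 (at least 22.5-fold lower) and Cxcl10 (a chemokine, at least 13.3-fold lower). Tmem176b and Tmem176a, a pair of neighbouring membrane protein genes, fell from 354 ± 85.2 to 3.67 ± 2.12 CPM and from 160 ± 39.7 to 3.02 ± 1.25 CPM. The genes named up to here in this paragraph had adjusted p of at most 0.0013 (Chil3) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Retnla, which encodes RELM-alpha, was at 442 ± 228 CPM against 0 UMIs (at least 126-fold; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.029), and its call ended without any of the 6 plates (edgeR adjusted p between 0.0524 without M-CSF replicate 3 and 0.0703 without IL-4 replicate 1).

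In the gene lists, 21 of the 26 measured members of the alternative activation list rose with IL-4 and 0 fell, also when adjusted over the list alone. Besides Arg1, these included Atp6v0d2 (a subunit of the proton pump, 1878 ± 163 against 94.0 ± 17.2 CPM). Of the 8 osteoclast markers, a list of another cell type, 6 rose and 0 fell, among them Itgb3 (integrin beta 3, 345 ± 91.6 against 7.23 ± 7.87 CPM). Dcstamp and Ocstamp, needed for macrophage fusion, had 248 and 207 UMIs against 1 and 1 (ratios 124, counting interval 22.1 to 4931, and 104, 18.4 to 4119). Of the 15 integrated stress response and amino acid synthesis genes 12 rose (14 adjusted over the list alone), among them Ddit3 (the transcription factor CHOP, 312 ± 62.8 against 42.3 ± 16.5 CPM) and Atf4 (its upstream regulator, 137 ± 15.3 against 36.7 ± 2.41). Of the 22 glycolysis and hypoxia genes 12 rose and 1 fell (12 and 1 adjusted over the list alone), among them Pfkp (a phosphofructokinase, 170 ± 22.9 against 33.5 ± 6.19 CPM). In the matrix list 7 of 16 rose and 4 fell (8 and 4 adjusted over the list alone), Mmp13, a collagenase, reaching 157 ± 18.3 CPM from 20.7 ± 9.67. The lists that moved down were the microglia signature (10 of 14 fell), complement and phagocytic receptors (14 of 23 fell, 3 rose), type I interferon-stimulated genes (17 of 27 fell, 1 rose) and interferon-inducible GTPases (6 of 18 fell). Adjusted over each list alone, 10, 14, 21 and 6 fell. C1qa, a chain of complement C1q, fell from 1311 ± 215 to 172 ± 15.8 CPM, Csf1r, the M-CSF receptor, from 2307 ± 196 to 493 ± 14.3, and Ifi27l2a, an interferon-inducible gene, from 806 ± 91.0 to 132 ± 0.486. Across the tumour-associated macrophage list 12 of 32 rose and 10 fell (13 and 10 adjusted over the list alone), and the list had no overall direction (camera adjusted p = 0.584). Its members went apart: Arg1 rose, whereas C1qa, C1qb (the B chain of C1q, 7297 ± 735 to 1626 ± 35.2 CPM) and Maf (a transcription factor of resident macrophages, 520 ± 24.7 to 43.8 ± 6.89) fell. In limma's camera test 14 of 28 lists passed, 7 in each direction, and 9 held with an estimated correlation, namely the 9 described above as moved. The 5 others lost the call, with adjusted p = 0.118 with an estimated correlation for MHC class I presentation (4 of 17 fell, 6 adjusted over the list alone) and for interferon-gamma effectors (2 rose and 9 of 24 fell, also adjusted over the list alone). It was adjusted p = 0.235 with an estimated correlation for cholesterol synthesis (5 of 17 rose, 6 adjusted over the list alone), adjusted p = 0.285 for mitochondrially encoded transcripts (4 of 12 fell) and adjusted p = 0.373 for DNA replication (1 of 18 rose). The camera call of the MHC class I list also ended without M-CSF replicate 1 (adjusted p = 0.055), that of the mitochondrial list without M-CSF replicate 3 (0.0509), and that of DNA replication without M-CSF replicate 1 (0.251), M-CSF replicate 3 (0.0509) or IL-4 replicate 3 (0.103). Ighm, an immunoglobulin gene of the lymphocyte marker list, fell with these groups from 528 ± 12.2 to 33.3 ± 15.4 CPM. The genes named so far in this paragraph had edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) of at most 8.4e-07, that of Atf4. Il6ra, the interleukin 6 receptor and the measured member of the mast cell and basophil list, fell from 49.4 ± 16.5 to 10.5 ± 2.47 CPM (edgeR adjusted p = 5.5e-05). The 4 measured neutrophil markers (S100a8, S100a9, Mmp8 and Csf3r) fell too, and 1 well of M-CSF replicate 3 held 539 neutrophil marker UMIs of its 1306. S100a8 went from −5.96 on the log2 scale (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0275) to −1.38 without M-CSF replicate 3 (edgeR adjusted p = 0.576) and −0.20 without neutrophil-rich cells (edgeR adjusted p = 0.888), a setting added after the data were seen, and its call also ended without any IL-4 plate (edgeR adjusted p between 0.0791 and 0.0885). The S100a9 call ended without any IL-4 plate (edgeR adjusted p between 0.0715 and 0.0770) and the Mmp8 call without IL-4 replicate 1 (0.147) or 3 (0.120).

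**Figure D2:**
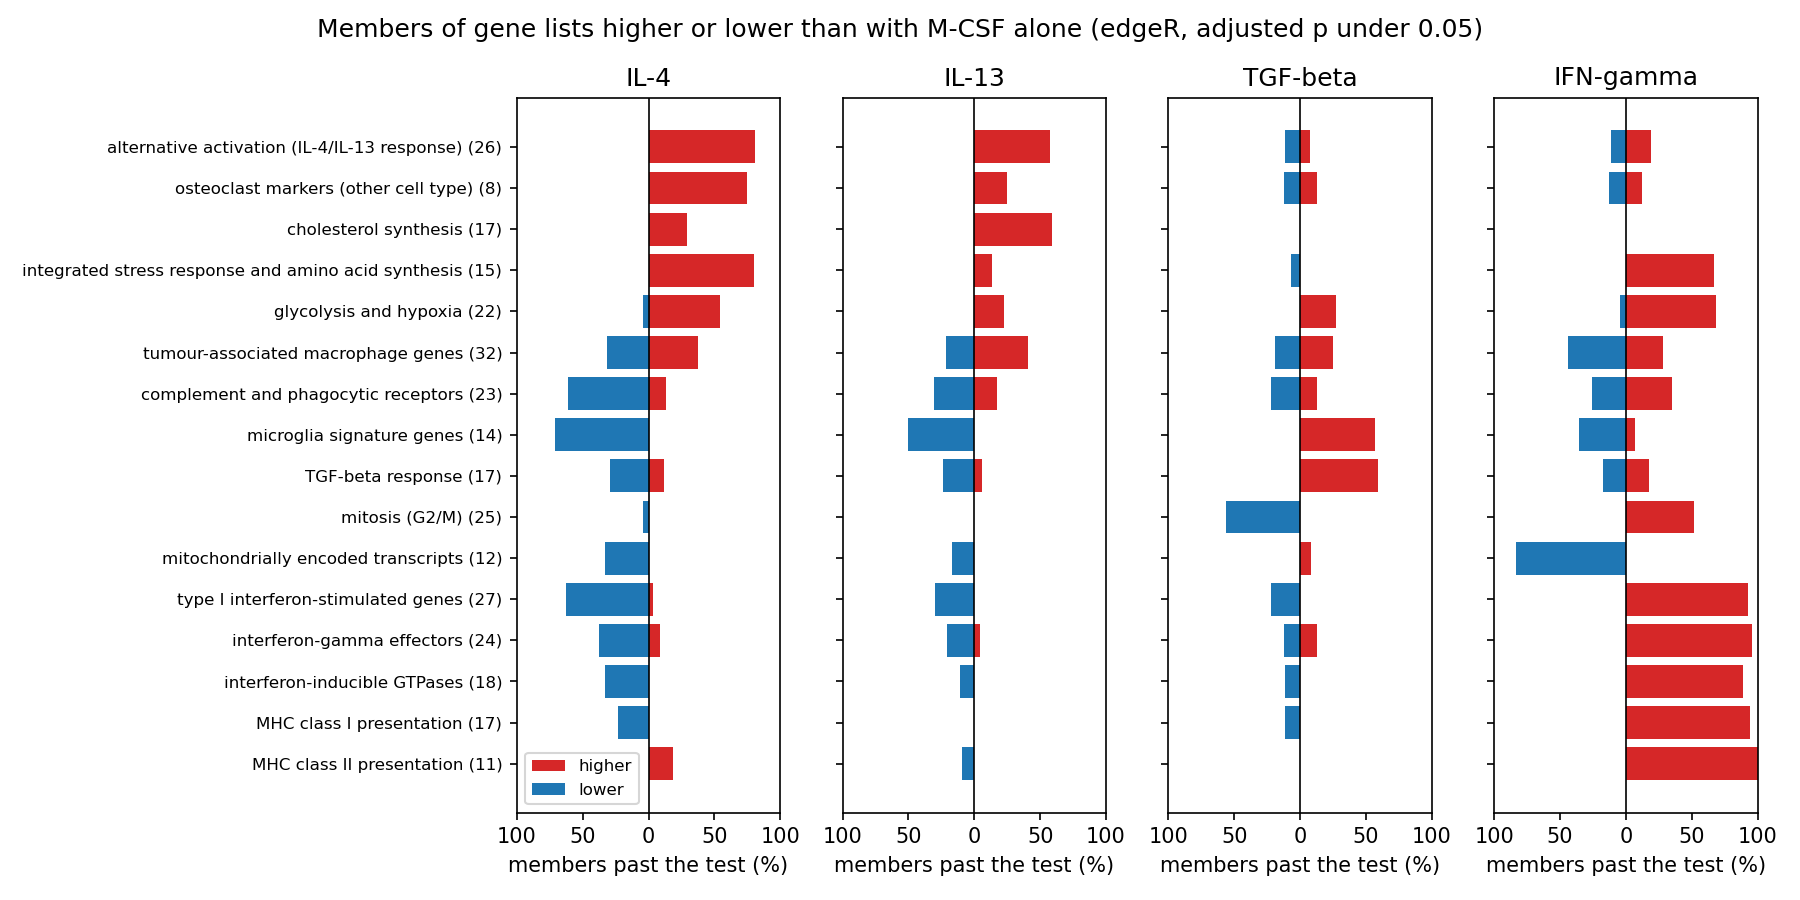
Percent of each list's measured members (numbers in parentheses) that were higher (red, to the right) or lower (blue, to the left) than with M-CSF alone at an adjusted p under 0.05 in edgeR's quasi-likelihood test, for IL-4, IL-13, TGF-beta and IFN-gamma. Only part of the 28 tested lists is drawn, and some that passed camera, such as the matrix list with IL-4, are left out. With IL-4, 21 of 26 alternative activation genes were higher, and with IFN-gamma 11 of 11 MHC class II genes.

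IL-13 shares a receptor chain with IL-4 and moved many of the same lists with fewer genes passing. Arg1 was at 179 ± 71.8 CPM (at least 50.9-fold above the 0 UMIs of M-CSF plates) and Rnase2a at 57.7 ± 12 CPM (at least 16.4-fold). Cholesterol synthesis genes rose, and Apoe fell to 5733 ± 773 CPM. In all 312 genes rose and 270 fell (182 and 190 by 2-fold or more), and 23.1% of the genes had groups that did not overlap, where chance gives 10%. Dhrs9, a retinol dehydrogenase, F10, coagulation factor X, and Flt1, the VEGF receptor 1, had ratios of counts of 62.7 (10.9 to 2507), 36.6 (9.85 to 307) and 37.4 (10.1 to 314) over 1, 2 and 2 UMIs in M-CSF plates. Tfrc, the transferrin receptor, rose from 24.8 ± 11.4 to 261 ± 56.4 CPM and Fabp4, a fatty acid binding protein, from 127 ± 26.6 to 914 ± 254. Mmp12, macrophage elastase, rose from 194 ± 140 to 2480 ± 452 CPM and Pparg, a lipid-sensing nuclear receptor, from 21.7 ± 11.3 to 95.2 ± 33.5. Cx3cr1, the fractalkine receptor, fell from 61.8 ± 14.9 to 4.59 ± 5.62 CPM and Tnf from 43.2 ± 15.3 to 5.37 ± 4.76. Fos, an immediate early gene, fell from 421 ± 66.8 to 71.3 ± 26.4 CPM and Ifit3, an interferon-stimulated gene, from 48.8 ± 26.9 to 3.50 ± 3.09. The genes named so far in this paragraph had edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) of at most 0.00069, that of Tnf. Chil3 was at 191 ± 153 CPM against 2 UMIs, a ratio of 90.8 (24.8 to 754; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.024). Its call ended without M-CSF replicate 1, 2 or 3 or IL-13 replicate 3 (edgeR adjusted p = 0.0965, 0.0956, 0.0644 and 0.0797).

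Of the alternative activation list 15 of 26 rose with IL-13 and 0 fell (16 and 0 adjusted over the list alone), and of the cholesterol synthesis list 10 of 17 rose and 0 fell (11 and 0 adjusted over the list alone). The latter included Fdps (farnesyl diphosphate synthase, 95 ± 16.1 against 17.9 ± 5.06 CPM) and Cyp51 (a sterol demethylase, 67.9 ± 22.3 against 8.89 ± 8.57). Of 8 osteoclast markers 2 rose (5 adjusted over the list alone), Itgb3 reaching 144 ± 35.3 CPM and Atp6v0d2, a member of both this list and the alternative activation list, 1158 ± 278. In the lipid uptake, storage and efflux list 8 of 21 rose and 3 fell (8 and 3 adjusted over the list alone), Lpl, lipoprotein lipase, going from 1010 ± 139 to 2813 ± 470 CPM and Cd36, a fatty acid scavenger receptor, from 336 ± 35.8 to 1087 ± 56.9. Of glycolysis and hypoxia genes 5 of 22 rose (9 adjusted over the list alone). The microglia signature (7 of 14 fell, 8 adjusted over the list alone) and type I interferon-stimulated genes (8 of 27 fell, 12 adjusted over the list alone) moved down. In camera 18 of 28 lists passed, 10 up and 8 down, and these 7 held with an estimated correlation. The tumour-associated macrophage list, with 13 of 32 members up and 7 down (13 and 8 adjusted over the list alone), passed in the upward direction (camera adjusted p = 0.0265) but had adjusted p = 0.0982 with an estimated correlation, and the call also ended without M-CSF replicate 2 (adjusted p = 0.0772). Members that rose included Lgals3 (galectin 3, 6178 ± 389 to 14340 ± 849 CPM) and Gpnmb (a lysosomal glycoprotein, 1746 ± 128 to 4366 ± 555). The other lists that lost the call had, with an estimated correlation, adjusted p = 0.116 for lysosome (8 of 30 rose, 1 fell), adjusted p = 0.123 for oxidative phosphorylation (7 of 41 rose) and adjusted p = 0.0780 for inflammatory cytokines and NF-kB targets (3 of 20 rose, 5 fell). Adjusted over the list alone, 11, 8 and 3 of these rose and 1, 0 and 11 fell. They also included, with an estimated correlation, complement and phagocytic receptors (4 of 23 rose, 7 fell; adjusted p = 0.155), matrix enzymes (4 of 16 rose, 1 fell; adjusted p = 0.0982) and immediate early and heat shock genes (3 of 17 rose, 7 fell; adjusted p = 0.112), where adjusted over the list alone 4, 4 and 4 rose and 10, 2 and 7 fell. The last 4 had, with an estimated correlation, adjusted p = 0.0604 for interferon-inducible GTPases (2 of 18 fell), adjusted p = 0.0982 for interferon-gamma effectors (1 of 24 rose, 5 fell), adjusted p = 0.120 for MHC class I presentation (0 of 17 passed) and adjusted p = 0.289 for DNA replication (1 of 18 rose). Without IL-13 replicate 3 or M-CSF replicate 1 the camera call also ended for MHC class I (adjusted p = 0.0645 and 0.0555) and DNA replication (0.0560 and 0.276). Ighm fell alongside to 266 ± 21.5 CPM. The genes named in this paragraph had edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) of at most 0.003, that of Ighm.

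The question whether IL-4 and IL-13 differ was tested on the plates of both. Relative to IL-13, IL-4 gave higher alternative activation, osteoclast marker and stress response genes and lower complement, cholesterol synthesis and microglia-type genes. Selenop (chromosome 15, 3268547 to 3280508, plus strand, mm10), the plasma selenium carrier, was at 248 ± 34.8 CPM with IL-4 and 3002 ± 226 with IL-13. In all 270 genes were higher with IL-4 and 412 lower (176 and 267 by 2-fold or more), with 28.1% of genes in groups that did not overlap, where chance gives 10%. Arg1 was higher with IL-4 by 1.52 ± 0.23 on the log2 scale, Rnase2a by 2.43 ± 0.27 and Itgax (CD11c) by 2.41 ± 0.25 (401 ± 16.5 against 76.3 ± 19.0 CPM). Mmp13 was higher by 3.98 ± 0.43 and Ch25h, cholesterol 25-hydroxylase, by 4.25 ± 0.48 (96.4 ± 10.6 against 4.28 ± 3.75 CPM). Lower with IL-4 were Tmem176b (3.67 ± 2.12 against 76.7 ± 13.2 CPM), Fcgr1, a high-affinity IgG receptor (17.7 ± 7.97 against 91.9 ± 11.8) and Maf (43.8 ± 6.89 against 203 ± 14.2). So were C1qa (172 ± 15.8 against 528 ± 47.9), C1qb (1626 ± 35.2 against 4683 ± 106), Csf1r (493 ± 14.3 against 1296 ± 18.6) and Tfrc (104 ± 16 against 261 ± 56.4). These genes had adjusted p of at most 6.9e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of the alternative activation list 17 of 26 were higher and 1 lower with IL-4 (17 and 2 adjusted over the list alone), of the osteoclast markers 5 of 8 higher (5 and 1 lower adjusted over the list alone). Of the stress response list 10 of 15 were higher (14 adjusted over the list alone) and of the matrix list 7 of 16 higher and 2 lower (also adjusted over the list alone). Of complement and phagocytic receptors 12 of 23 were lower and 4 higher (14 and 4 adjusted over the list alone). Of cholesterol synthesis genes 4 of 17 were lower (10 adjusted over the list alone) and of the microglia signature 4 of 14 lower (4 adjusted over the list alone). These 7 of the 10 lists past the camera threshold (7 up, 3 down) held with an estimated correlation. Immediate early and heat shock genes (4 of 17 higher, 5 adjusted over the list alone) had adjusted p = 0.0630 with an estimated correlation, dendritic cell markers (2 of 5 higher, 3 adjusted over the list alone) adjusted p = 0.159 and glycolysis (1 of 22 higher) adjusted p = 0.159. The glycolysis call also ended without IL-13 replicate 1 (adjusted p = 0.103), IL-4 replicate 2 (0.0740) or IL-4 replicate 3 (0.0693). Ighm was lower with IL-4 by 2.96 ± 0.29 on the log2 scale. Without IL-4 replicate 1 the count of lower genes was 245, and without IL-4 replicate 2 that of higher genes was 174.

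Against the shared M-CSF plates, IL-4 and IL-13 both raised 257 genes and both lowered 238, with 1 gene in opposite directions. Independent lists of these sizes would share 34.7 and 32.0. Over the 7098 genes the log2 fold changes had a correlation of 0.76 and a covariance of 0.708. Unchanged groups simulated with redrawn M-CSF plates common to both contrasts gave 0.57 and 0.0909, a difference in covariance of 0.617. The simulated correlation comes from noise in the shared plates alone and is no bound for changed groups. Part of the overlap may come from the shared controls, and 3 control plates do not allow a split.

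IL-10, a cytokine that dampens inflammatory responses, changed 5 genes past the threshold, so all 5 are named. Cd5l (chromosome 3, 87357881 to 87371073, plus strand, mm10), which encodes a secreted scavenger protein of macrophages, rose from 66.9 ± 9.99 to 252 ± 57.4 CPM. AW112010, an interferon-inducible transcript, rose from 87.7 ± 13.6 to 249 ± 98.4, Cd72, a lectin receptor, from 128 ± 40.4 to 267 ± 48.5 and Ifi27l2a from 806 ± 91.0 to 1514 ± 386. Zfp36, an RNA-binding protein that destabilises cytokine mRNAs, fell from 318 ± 84.4 to 128 ± 13.7. The edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) were 0.00062, 0.00023, 0.037, 0.0023 and 0.032, and 509 genes had an unadjusted p under 0.05. No call held in every leave-one-out fit of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Without IL-10 replicate 2 the adjusted p was 0.227 for Cd5l, 0.429 for AW112010 and 0.227 for Zfp36, and without IL-10 replicate 3 it was 0.375 for Ifi27l2a, 0.389 for Cd72 and 0.273 for Zfp36 (edgeR). The Cd72 call also ended without M-CSF replicate 1 (edgeR adjusted p = 0.167) or 3 (0.434), and the Zfp36 call without M-CSF replicate 1 (0.0627) or 3 (0.358). The count was 10 genes up and 0 down without IL-10 replicate 3 and 4 up and 2 down without IL-10 replicate 2, where the lone plate is assumed to vary like the other groups. Without M-CSF replicate 1 or 3 the count of genes down was 0 in edgeR, as the Zfp36 call ended. Of the IL-10 response list 0 of 18 members passed, also adjusted over the list alone, and camera gave adjusted p = 0.245. Camera passed 7 lists, and 0 held with an estimated correlation. Higher were interferon-gamma effectors (adjusted p = 0.125 with an estimated correlation), type I interferon-stimulated genes (adjusted p = 0.369) and MHC class II presentation (adjusted p = 0.430). Lower were immediate early and heat shock genes (adjusted p = 0.0588 with an estimated correlation), NRF2 oxidative stress genes (adjusted p = 0.0728), the microglia signature (adjusted p = 0.125) and NF-kB targets (adjusted p = 0.287). Adjusted over the list alone, 6 of 24 interferon-gamma effectors, 3 of 27 interferon-stimulated genes and 1 of 11 MHC class II genes were higher, and 6 of 17 immediate early and heat shock genes and 4 of 20 NF-kB targets lower. Without IL-10 replicate 2, 3 lists passed in camera, without IL-10 replicate 3, 9, and without M-CSF replicate 3, 4. Without IL-10 replicate 2 the MHC class II list turned to lower (camera adjusted p = 0.317) and the calls ended for interferon-gamma effectors (0.0938), the microglia signature (0.153) and NRF2 genes (0.195). Without IL-10 replicate 3 they ended for interferon-stimulated genes (camera adjusted p = 0.423) and NF-kB targets (0.494). Without an M-CSF plate, camera calls ended for MHC class II (adjusted p = 0.115 without replicate 2 and 0.173 without 3), interferon-stimulated genes (0.211 without 2 and 0.0703 without 3), the microglia signature (0.0558 without 2) and NF-kB targets (0.0511 without 1 and 0.0572 without 3). The plates of this group stood apart from each other. The MHC class II list was at 2654 CPM of all UMIs in replicate 2 (Poisson interval 2488 to 2828) and 394 in replicate 3 (325 to 472). M-CSF plates ran from 489 to 976 CPM, between these values. Replicate 2 also held transcripts of T and NK cells such as Nkg7, a cytotoxic granule protein (173 CPM in replicate 2 and 0 UMIs in the 16 other plates), singled out after its values were seen. Over the 380 wells of replicate 2, the share of the 18 genes nearly absent from the other plates and that of 3 MHC class II genes had a correlation of −0.035. Genes outside those 18 also differed between the IL-10 plates. In CPM of all UMIs, Ccl17 was at 246 in replicate 2 and 3.42 in replicate 3, Chil3 at 154 and 6.84, Ear2 at 78.3 and 0, and Mgl2 at 58.7 and 0. These were picked after the values were seen.

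TGF-beta raised genes of the microglia signature and of the TGF-beta response and lowered mitosis genes. For the mitosis list the call was lost, with adjusted p = 0.0729 with an estimated correlation. Cx3cr1 (chromosome 9, 119901616 to 120069879, minus strand, mm10) rose from 61.8 ± 14.9 to 585 ± 126 CPM, Apoe from 18391 ± 2862 to 56531 ± 13321, and Mrc1, the mannose receptor, fell from 465 ± 68 to 23.3 ± 10.7. In all 289 genes rose and 294 fell (219 and 203 by 2-fold or more), and 21.9% of the genes had groups that did not overlap, where chance gives 10%. Hp, haptoglobin, a member of the monocyte marker list, was at 115 ± 32.1 CPM against 0 UMIs with M-CSF alone (at least 32.8-fold), and Mmp2, a gelatinase, at 37.0 ± 5.92 CPM against 0 UMIs (at least 10.5-fold). Apoc1, an apolipoprotein encoded next to Apoe, rose from 19.3 ± 4.86 to 283 ± 62.6 CPM, and Fam46c, a poly(A) polymerase, from 7.80 ± 2.52 to 153 ± 52.2. Pmepa1, a feedback inhibitor of TGF-beta signalling, and Cav1, caveolin 1, had ratios of counts of 37.4 (12.4 to 185) and 47.7 (8.05 to 1934). Genes at 0 UMIs with TGF-beta were Ccl12 (a monocyte chemokine, at least 7.07-fold lower), Ube2c (a ubiquitin-conjugating enzyme of mitosis, at least 6.78-fold), Tmem209 (a nuclear envelope protein, at least 6.44-fold) and Spaca9 (at least 5.64-fold). Ccl3, an inflammatory chemokine, fell from 263 ± 28.2 to 22 ± 14.5 CPM, and Cfp, properdin of the complement system, from 707 ± 90.8 to 115 ± 28.9. The genes named here had edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) of at most 0.0035, that of Mmp2. Without TGF-beta replicate 2 the count of genes that fell was 185.

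Of the microglia signature 8 of 14 rose with TGF-beta and 0 fell (10 and 0 adjusted over the list alone), among them Olfml3 (a secreted protein, 22.9 ± 13.9 to 205 ± 57.5 CPM) and Tgfbr1 (the type I TGF-beta receptor, 406 ± 54.9 to 1412 ± 161). Of the TGF-beta response list 10 of 17 rose and 0 fell (12 and 0 adjusted over the list alone), among them Id3 (an inhibitor of helix-loop-helix factors, 49.7 ± 25.1 to 455 ± 105 CPM). Of the mitosis list 14 of 25 fell and 0 rose (19 and 0 adjusted over the list alone), among them Cdca3 (141 ± 49.9 to 17.9 ± 11.7 CPM) and Birc5 (survivin, 80.1 ± 28.0 to 13.5 ± 9.23), and of DNA replication genes 4 of 18 fell (7 adjusted over the list alone). These last lists passed camera (adjusted p = 4.76e-11 and 0.000215) and lost the call with adjusted p = 0.0729 with an estimated correlation for mitosis and adjusted p = 0.129 for replication. In camera 14 of 28 lists passed, 8 up and 6 down, and the microglia signature and TGF-beta response held with an estimated correlation. The lists that lost the call with adjusted p = 0.0729 with an estimated correlation were also type I interferon-stimulated genes (6 of 27 fell, 12 adjusted over the list alone), lipid uptake, storage and efflux (6 of 21 rose, 3 fell, 8 and 3 adjusted over the list alone) and mitochondrially encoded transcripts (1 of 12 rose, 5 adjusted over the list alone). Glycolysis and hypoxia (6 of 22 rose) and the matrix list (4 of 16 rose) had adjusted p = 0.0859 with an estimated correlation, NF-kB targets (6 of 20 fell) 0.0945 and lysosome (5 of 30 rose, 4 fell) 0.194. Adjusted over the list alone, 8, 5, 0 and 8 of these rose and 1, 1, 7 and 5 fell. With an estimated correlation interferon-inducible GTPases (2 of 18 fell) had adjusted p = 0.0945, immediate early and heat shock genes (4 of 17 fell, 5 adjusted over the list alone) adjusted p = 0.142 and macrophage transcription factors (5 of 25 rose, 2 fell, 6 and 2 adjusted over the list alone) adjusted p = 0.418. Without M-CSF replicate 1 the camera call also ended for the matrix list and GTPases (adjusted p = 0.0828 each), heat shock genes (0.0583) and transcription factors (0.0575). For GTPases and transcription factors it ended too without M-CSF replicate 3 (0.0542 and 0.117), TGF-beta replicate 1 (0.0509 and 0.0556) and TGF-beta replicate 2 (0.109 each). Of lysosomal genes, Ctsd, cathepsin D, rose from 9434 ± 411 to 23121 ± 1218 CPM. Of the tumour-associated macrophage list 8 of 32 rose and 6 fell (11 and 8 adjusted over the list alone; camera adjusted p = 0.170), Cd9, a tetraspanin, rising from 314 ± 18.4 to 988 ± 40.7 CPM. Ighm fell alongside, from 528 ± 12.2 to 35.3 ± 25.4 CPM. The genes named so far in this paragraph had edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) of at most 0.00028, that of Birc5. Of the 4 measured neutrophil markers Csf3r, the G-CSF receptor, rose from 39.1 ± 8.33 to 101 ± 22.7 CPM (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0162). Its call ended without M-CSF replicate 2 (edgeR adjusted p = 0.0869), M-CSF replicate 3 (0.0528) or TGF-beta replicate 1 (0.105), with no filter on low counts (0.0576), in cells of 1000 UMIs or more (0.222) and without cycling cells (0.0837). S100a8 had a log2 difference of −2.70 (edgeR adjusted p = 0.339) and of 2.33 without neutrophil-rich cells (edgeR adjusted p = 0.0132).

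IFN-gamma, the main macrophage-activating cytokine of T and NK cells, raised nearly all measured interferon-inducible and antigen presentation genes. Ly6a (chromosome 15, 74994877 to 74998031, minus strand, mm10), the surface protein Sca-1, rose from 11 ± 4.33 to 5352 ± 403 CPM. Gbp4 and Gbp2b, guanylate-binding proteins, were at 329 ± 44.7 and 182 ± 17.5 CPM against 0 UMIs with M-CSF alone (at least 93.4-fold and 51.7-fold). In all 684 genes rose and 555 fell (489 and 360 by 2-fold or more), and 30.8% of the genes had groups that did not overlap, where chance gives 10%. Further genes at 0 UMIs with M-CSF alone were AA467197 (338 ± 21.6 CPM, at least 96.1-fold), Cnn3 (calponin 3, 141 ± 19.5 CPM, at least 40.1-fold) and Serpina3f (a protease inhibitor, 137 ± 22.7 CPM, at least 39.1-fold). Serpina3g (535 ± 21.4 CPM, at least 152-fold) and Cxcl9, a T cell chemokine (131 ± 40.1 CPM, at least 37.1-fold), passed in edgeR and not in DESeq2 (adjusted p = 0.209 and 0.365). Genes that fell were Ms4a4a, a membrane protein of resident-type macrophages (1793 ± 252 to 16.3 ± 9.74 CPM), Fcrls, a microglia marker (1121 ± 236 to 27.2 ± 18.8), Apoe (to 1567 ± 103.1), Mrc1 (to 42.5 ± 3.16), Stab1, a scavenger receptor (523 ± 87.7 to 38.4 ± 4.55), and Maf (to 92.1 ± 18.2). Hpgd, a prostaglandin dehydrogenase, and Cxcr4, a chemokine receptor, were at 0 UMIs with IFN-gamma (at least 17.8-fold and 12.4-fold lower). Cd5l and Cbr2, a carbonyl reductase, had 1 UMI each with IFN-gamma, ratios of 95 (16.4 to 3818) and 113 (19.6 to 4530). The genes named here had edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) of at most 7.8e-06, that of Hpgd.

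With IFN-gamma, 23 of 24 interferon-gamma effectors, 16 of 18 interferon-inducible GTPases, 25 of 27 type I interferon-stimulated genes, 16 of 17 MHC class I genes and 11 of 11 MHC class II genes rose, and 0 fell. Adjusted over each list alone the counts were 24, 18, 26, 17 and 11. Examples are Igtp (an interferon-inducible GTPase, 42.7 ± 22.8 to 852 ± 125 CPM), Irf7 (27.3 ± 20.7 to 265 ± 3.62), H2-K1 (1056 ± 57.0 to 2918 ± 124) and H2-DMa (73.6 ± 8.68 to 874 ± 33.0). Members of these families have near-identical copies, so their UMIs may be split between copies and single members are uncertain. Of glycolysis and hypoxia genes 15 of 22 rose and 1 fell (19 and 1 adjusted over the list alone), Hk3, a hexokinase, rising from 87.5 ± 19.0 to 503 ± 36.8 CPM. Of mitochondrially encoded transcripts 10 of 12 fell (10 adjusted over the list alone), mt-Cytb from 7196 ± 820 to 2804 ± 598 CPM, and of the microglia signature 5 of 14 fell and 1 rose (7 and 1 adjusted over the list alone). The tumour-associated macrophage list had 14 of 32 members down and 9 up (also adjusted over the list alone) and moved down (camera adjusted p = 6.26e-05; adjusted p = 0.0146 with an estimated correlation). Its mean log2 change was 0.06 and its median −0.33, so mean and test differ in sign, and the call ended with no filter on low counts (camera adjusted p = 0.651). Members that fell included Mrc1, Apoe, Ctsd (9434 ± 411 to 2737 ± 377 CPM) and Maf. In camera 14 of 28 lists passed, 9 up and 5 down, and 9 held with an estimated correlation, the lists given so far. Mitosis genes (13 of 25 rose, 19 adjusted over the list alone), with Top2a, a DNA topoisomerase, rising from 40.1 ± 16.2 to 126 ± 3.46 CPM, had adjusted p = 0.110 with an estimated correlation. So did lysosomal genes (15 of 30 fell, 3 rose, 16 and 5 adjusted over the list alone; adjusted p = 0.110) and immediate early and heat shock genes (8 of 17 fell, 2 rose; adjusted p = 0.110). Integrated stress response genes (10 of 15 rose, 12 adjusted over the list alone) had adjusted p = 0.0858 and DNA replication (2 of 18 rose) adjusted p = 0.413 with an estimated correlation, and the replication call also ended without M-CSF replicate 1 (camera adjusted p = 0.322) or IFN-gamma replicate 1 (0.0626). The share of mitochondrial UMIs, a sign of RNA quality, was 1.91% in IFN-gamma plates and 3.40% in M-CSF plates, and Ighm fell from 528 ± 12.2 to 35.2 ± 17 CPM. The genes named so far in this paragraph had edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) of at most 0.00017, that of Top2a. The neutrophil marker S100a9 passed as lower (128 ± 208 CPM with M-CSF alone and 1.44 ± 1.31, or 2 UMIs, with IFN-gamma, a ratio of counts of 65.5, interval 17.6 to 551; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0407). Its call ended without any IFN-gamma plate (edgeR adjusted p between 0.0975 and 0.118), with no filter on low counts (0.113), with plates thinned to the smallest total (0.154) and in embedded cells (0.0670), and it was under the filter on low counts without M-CSF replicate 3 and without neutrophil-rich cells. Il6ra of the mast cell and basophil list fell from 49.4 ± 16.5 to 22.4 ± 9.42 CPM (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0411). Its call ended without M-CSF replicate 1 (edgeR adjusted p = 0.268) or 2 (0.0725) or IFN-gamma replicate 2 (0.179) or 3 (0.0810), in DESeq2 (adjusted p = 0.0785) and in the other settings on all plates or the compared plates, except RLE scaling, the replicate block and no neutrophil-rich cells (edgeR adjusted p between 0.0502 and 0.758).

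Within plates, the share of cells that responded was counted after each cell was thinned to 1000 UMIs. A cell responded when its UMIs of the list for that cytokine exceeded the 95th percentile of M-CSF cells. This bound lay near the mean of some groups. It was over 4 UMIs for TGF-beta, whose plates averaged 3.50 to 3.89 list UMIs per cell. For IL-13 it was over 3, with plate means of 3.01 to 3.90. Such a share therefore cannot tell a response in part of the cells from a modest one in all cells. Alternative activation genes marked 73.0 ± 5.08% of IL-4 cells and 38.2 ± 7.37% of IL-13 cells against 2.91 ± 1.32% of M-CSF cells (SD, n = 3). The TGF-beta response list marked 32.3 ± 4.92% of TGF-beta cells against 3.15 ± 1.20%, and interferon-inducible GTPases marked 92.3 ± 1.5% of IFN-gamma cells against 2.02 ± 2.73%. Each of these, and IL-4 against IL-13, had a two-sided exact permutation p of 0.1, the smallest that 3 plates against 3 allow. Lists also marked cells of other cytokines. Alternative activation genes marked 12.7 ± 2.16% of IFN-gamma cells and 7.57 ± 2.99% of IL-10 cells (n = 2), and the TGF-beta response list 10.4 ± 3.40% of IFN-gamma cells. Interferon-inducible GTPases averaged at most 2.12% with another cytokine (IL-10). The IL-10 response list marked 3.03 ± 0.861% of IL-10 cells (n = 2) against 4.58 ± 1.72% of M-CSF cells (exact permutation p = 0.5), and the sign of this difference turned without M-CSF replicate 1 (0.858%) or 3 (5.04%). Without thinning the shares were 66.3%, 30.4%, 12.5%, 70.0% and 3.68% for IL-4, IL-13, TGF-beta, IFN-gamma and IL-10. Thinning kept 646, 411, 227, 548, 234 and 284 cells of IL-4, IL-13, TGF-beta, IFN-gamma, IL-10 and M-CSF plates and left out 494, 729, 913, 592, 526 and 856. Among responding cells, IL-4 cells had 8.71 ± 1.01 and IL-13 cells 6.48 ± 0.308 UMIs of the alternative activation list (exact permutation p = 0.1, the smallest possible).

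Cells with 2 or more UMIs of the mitosis list, called cycling here, made up 20 ± 0.451% of thinned M-CSF cells. The share was 3.30 ± 2.94% with TGF-beta and 31.3 ± 1.28% with IFN-gamma (exact permutation p = 0.1 each, the smallest possible). It was 15.8 ± 0.736% with IL-10 (exact permutation p = 0.1), 17.9 ± 3.21% with IL-4 (p = 0.4, exact) and 19.8 ± 5.55% with IL-13 (p = 1, exact). Without thinning the shares were 9.65%, 2.11%, 22.9%, 10.3%, 17.5% and 11.8% for M-CSF, TGF-beta, IFN-gamma, IL-10, IL-4 and IL-13. The difference from M-CSF plates thus turned in sign with IL-10 (exact permutation p = 0.9), IL-4 (p = 0.1, exact) and IL-13 (p = 0.4, exact). Thinning kept the deeper cells only, 284 of 1140 with M-CSF alone, while unthinned groups differ in depth. The direction with these cytokines is therefore not settled.

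**Figure D3:**
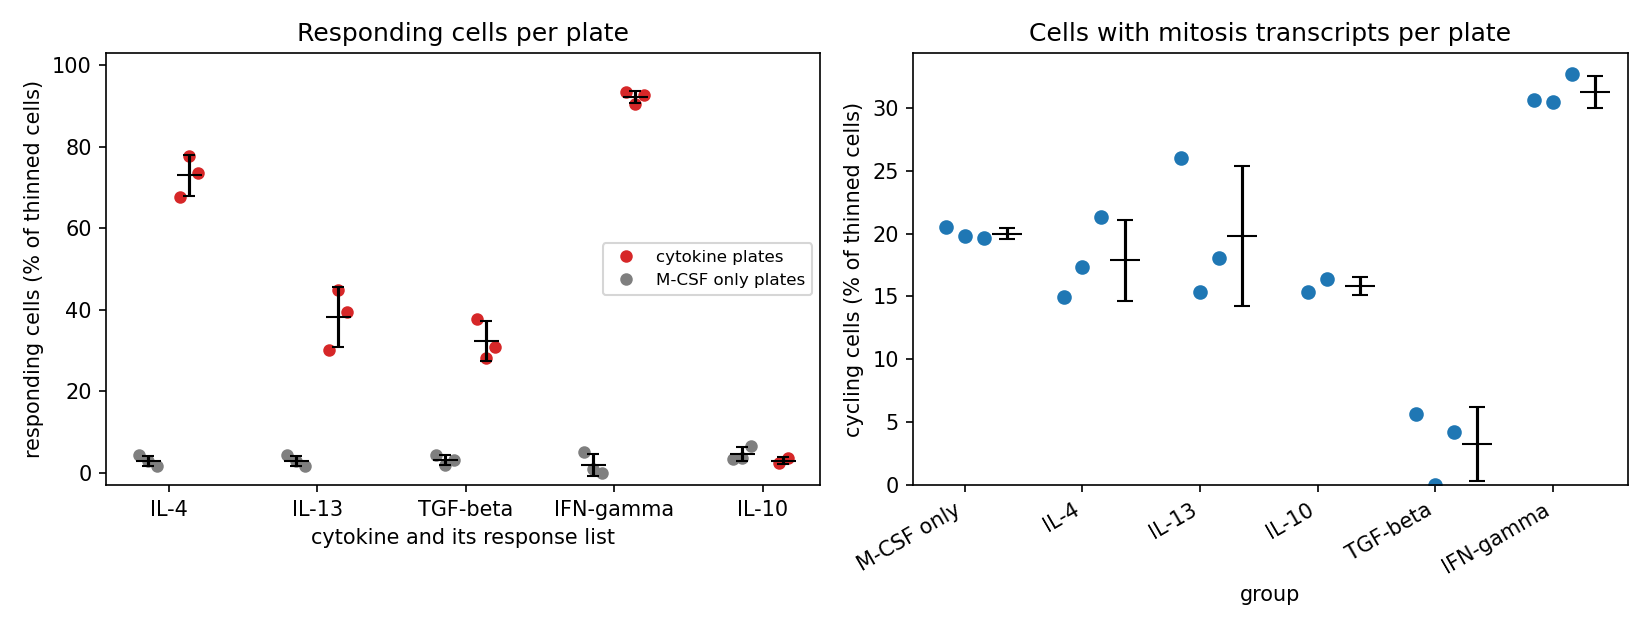
Left, percent of cells thinned to 1000 UMIs that responded (vertical axis) in each cytokine's plates (red points) and in M-CSF plates (grey points) for that cytokine's list (horizontal axis). Right, percent of thinned cells with 2 or more mitosis UMIs per plate (blue points) in each group; black bars and whiskers are mean and SD. Responding cells average 92.3% with IFN-gamma and 3.03% with IL-10, and cycling cells 3.30% with TGF-beta.

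Across single cells, the question was whether cells with a Zeb2 UMI carried more tumour-associated macrophage transcripts. Of 2350 cells thinned to 1000 UMIs, 18.6% had a Zeb2 UMI. The share per group ran from 13.3 ± 3.09% with IFN-gamma to 20.8 ± 1.24% with IL-4, against 18.2 ± 5.93% with M-CSF alone, with exact permutation p of 0.3 or more. The list's UMIs in cells with a Zeb2 UMI over those without had a median log2 ratio of −0.06 over 17 plates (−0.17 to 0.10), with 4 plates above 0 (exact sign test p = 0.049). This value lay at percentile 13.5 of 200 genes detected in a like share of cells, whose median was −0.02. The sign test did not pass with cells thinned to 500 UMIs (−0.02, exact p = 0.332) or 2000 UMIs (−0.06, exact p = 0.21) or without cycling cells (−0.07, exact p = 0.332).

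Cells rich in markers of another cell type were counted as those with 5 or more UMIs and over 2% of their UMIs from a list. Of 6460 cells, 2780 met this for the monocyte list, 6 for the neutrophil list and 1 for the lymphocyte list. The monocyte list includes Lyz2, lysozyme, which macrophages also express abundantly and which held 96.4% of the list's UMIs, so that this count does not measure monocytes. Without Lyz2, 2 of 6460 cells met it, and for the neutrophil list without S100a8 3 did. For dendritic cell, mast cell and basophil, osteoclast, stromal and endothelial, and erythroid and megakaryocyte markers the count was 0 of 6460, which allows up to 0.0464% of cells past this threshold. It does not limit the share of those cell types, since 4128 of the cells had 500 UMIs or more, and 1 member of the mast cell and basophil list and 0 of the stromal list were over 3 UMIs in M-CSF plates. The osteoclast markers summed to 163 ± 26.8 CPM of all UMIs with M-CSF alone, 2580 ± 206 with IL-4 and 1350 ± 272 with IL-13. Atp6v0d2 held 69.6% of the list's UMIs, and without it the sums were 72.7 ± 13.3, 738 ± 54.6 and 248 ± 14 CPM. The monocyte markers summed to 31283 ± 6179 CPM with M-CSF alone, 49818 ± 7137 with TGF-beta, 22242 ± 5171 with IL-10, 18224 ± 295 with IL-13, 15820 ± 1319 with IL-4 and 9094 ± 1313 with IFN-gamma. Without Lyz2 they summed to 573 ± 89.1 CPM with M-CSF alone, 371 ± 34.1 with TGF-beta, 643 ± 139 with IL-10, 933 ± 55.9 with IL-13, 858 ± 58.3 with IL-4 and 935 ± 216 with IFN-gamma. The dendritic cell markers summed to 166 ± 38.0 CPM with M-CSF alone and 514 ± 34.9 with IL-4, and without Itgax to 161 ± 33.4 and 120 ± 35.0. Monocyte markers (9 measured) and dendritic cell markers (5 measured) had no camera call against M-CSF alone with any of the 5 cytokines. Of the monocyte markers 1 rose and 4 fell with IL-4, 1 rose and 2 fell with IL-13, 2 rose and 2 fell with TGF-beta and 3 rose and 2 fell with IFN-gamma. Adjusted over the list alone these were 1 and 4, 1 and 3, 2 and 3, and 3 and 2. Of the dendritic cell markers 3 rose and 1 fell with IL-4, 1 rose and 1 fell with IL-13 (2 and 1 adjusted over the list alone), 0 passed with TGF-beta and 1 rose and 1 fell with IFN-gamma.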

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

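The comparison of MHC class II levels between the IL-10 plates, the depth tests of mitosis transcripts, both tests on IL-13 and the splits of plates were chosen after the results were seen.

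The 4 empty wells of IL-10 replicate 2 had a median of 72.5 UMIs, above the highest empty well of M-CSF plates at 35, and this stood out as signal in wells that no comparison uses. Single empty wells above 35 UMIs were also found in other plates: the highest was in IL-10 replicate 3 (104 UMIs, against 96 in replicate 2), and IL-4, IL-13 and IFN-gamma plates reached 45, 37 and 36.

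IL-10 replicate 2 held 18 genes that were nearly absent elsewhere, with 189 UMIs in 82 wells, among them Nkg7 (62 UMIs), Cd3g (16), Cd8b1 (10) and Gzmb (9), genes of T and NK cells. Whole cells of another type in place of macrophages are argued against: the 26 wells with 3 or more such UMIs had 94.8% (79.6 to 109) of the macrophage marker share of the other wells, though a cell beside a macrophage in 1 well stays open. The IL-10 treatment itself cannot be told apart for MHC class II: replicate 2 was at 6.74 times the level of replicate 3, but 1 plate against 1 gives no spread between plates. The rule set beforehand against free RNA spread evenly over the wells asked for a correlation above all 1000 permutations. Nkg7 and the other genes had a correlation of 0.318 over wells and 2 of 1000 permutations were as high, so by this rule it cannot be told apart from other sources. The UMIs were uneven, with 9 in the highest well and 3 or more in 26 of 380 wells. Those 26 wells were also deeper, with a median of 1218 UMIs against 705.5 in the others, and this is 1 plate. RNA from a library outside these plates also stays open and was not analysed here.

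The lower share of cycling cells with TGF-beta and the higher share with IFN-gamma could come from depth or from abundant genes. At 1 depth the difference from M-CSF plates was −16.7 percentage points with TGF-beta and 11.3 with IFN-gamma, which argues against depth. Without the 50 most abundant genes, at 500 UMIs, it was −10.7 and 9.90 points, each larger than the sum of both SDs. SDs over so few plates can fall below counting error, as that of M-CSF plates at 1000 UMIs did (0.451 points). A change in cycling with these cytokines is an open hypothesis, found on the same data, and rests on cells with 2 or more mitosis UMIs. Free RNA in the wells was not tested, and the mitosis list had adjusted p = 0.0729 with TGF-beta and 0.110 with IFN-gamma with an estimated correlation.

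IL-13 changed fewer genes than IL-4 on plates of lower depth. With all plates thinned to 1 total, IL-4 changed 1240 genes and IL-13 470, a ratio of 2.64, which argues against depth as the whole cause. If IL-13 acted on fewer cells with an otherwise equal response, few genes should lie past both groups: 35 of the 582 genes changed by IL-13 did, 6.01% (exact binomial interval 4.22 to 8.26). On this count fewer responding cells cannot be told apart from a different response, because the interval spans the 5% set as the bound. Both contrasts behind the count also use the same IL-13 plates, whose noise can add to it. The interval treats genes as independent, which they are not. A weaker response in all cells would likewise place IL-13 between M-CSF and IL-4, so the count cannot separate it from fewer responding cells. The 25 that lay above both groups include the fatty acid binding protein Fabp4 and the transferrin receptor Tfrc. For cholesterol synthesis genes, looked at here after the results were seen, list sums argue against an equal response in fewer cells. They were 445 ± 45.1 CPM of all UMIs with M-CSF alone, 722 ± 9.44 with IL-4 and 1017 ± 180 with IL-13 (SD, n = 3). The lowest IL-13 plate was at 816 CPM and the highest IL-4 plate at 732. Single members were less firm. Between IL-4 and IL-13 the Cyp51 call ended without IL-13 replicate 2 (edgeR adjusted p = 0.289) or 3 (0.0622) or any IL-4 plate (0.105 to 0.114). The Fdps call ended without IL-13 replicate 3 (edgeR adjusted p = 0.109) or IL-4 replicate 1 (0.0818) or 2 (0.0843). For the alternative activation list IL-13 lay between, at 3555 ± 547 CPM against 843 ± 123 with M-CSF alone and 6715 ± 615 with IL-4.

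Plates of 3 against 3 can be split in 10 ways, too few for a share under 0.05. Fitted on the 6 plates alone, the real split changed 1662 genes for IL-4 (highest other 0), 523 for IL-13 (0), 462 for TGF-beta (2), 1080 for IFN-gamma (2) and 911 for IL-4 against IL-13 (0), and in each case 1 split, the real one, gave as many. Every other split mixes plates of both groups, so a real difference enters the spread within groups and few genes can pass. Their counts are therefore no measure of chance.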

How the results depend on the processing

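The settings on embedded cells, wells over 5 times the median, neutrophil-rich cells and marker lists without the member with most UMIs were chosen after the data were seen. RLE scaling kept 12 of 12 gene counts within 1.5 times and 726 of 729 named genes on their side of the threshold. Named-gene calls that ended were 38 of 729 in DESeq2, 68 of 679 in cells of 1000 UMIs or more and 87 of 569 with each cell thinned to 1000 UMIs, and no setting moved the median of all genes by over 0.05. Embedded cells alone moved no gene or list count past 1.5 times, and wells of 500 UMIs or more gave 0 IL-10 genes down (edgeR, 477 genes at an unadjusted p under 0.05) and moved no other count that far. Plate sums thinned to the smallest total, which lowers depth alone, moved 1 of 12 gene counts. Both settings that moved 11 of 12 kept 2350 of 6460 cells, so that depth and the number of cells are not separated there. In cells of 1000 UMIs or more the genes up and down were 468 and 491 for IL-4, 204 and 166 for IL-13, 7 and 3 for IL-10, 181 and 178 for TGF-beta (9 lists), 431 and 327 for IFN-gamma, and 150 up for IL-4 against IL-13. With each cell thinned to 1000 UMIs they were 348 and 380, 140 and 133, 2 down for IL-10, 123 and 102 (8 lists), 336 and 267, and 122 and 195 (6 lists), where fewer cells and UMIs are left by construction. With an estimated correlation 9 lists passed for IL-4, 7 for IL-13, 0 for IL-10, 2 for TGF-beta and 9 for IFN-gamma, and 0 for IL-10 with fry. With no filter 22 lists passed for IL-4, and IL-10 had 11 genes up and 6 down. IL-10 genes down were 4 with plates thinned to the smallest total (4 lists), 3 without cycling cells, 2 without wells over 5 times the median and 4 in a fit of the compared plates alone. Replicate numbers did not pair the plates (same-number correlations −0.19 to 0.20), and a replicate block gave 3 IL-10 genes down and moved no other count past 1.5 times; it ended 10 and added 5 of 729 named-gene calls. The Zeb2 change with IFN-gamma was −0.57 with no filter (adjusted p = 0.0539), −0.52 in cells of 1000 UMIs or more (0.204) and −0.61 in DESeq2 (0.0717), all no longer past the threshold; over its alternatives the adjusted p ran from 0.00648 to 0.204. Zeb2 across cells was −0.0194 at 500 UMIs, −0.0602 at 2000 and −0.0676 without cycling cells. Turned in sign were the mitosis list with IL-4 in cells of 1000 UMIs or more (signed −log10 p −1.67, adjusted p = 0.0446, range 0.0446 to 0.994) and S100a8 with TGF-beta without neutrophil-rich cells (log2 2.33, edgeR adjusted p = 0.0132, range 0.0132 to 0.654). So were the MHC class II list with IL-10 without IL-10 replicate 2 (signed −log10 p −0.908 to 13.2 with 1 plate left out) and the IL-10 responding share (0.858% and 5.04% without M-CSF replicates 1 and 3). The shares of cycling cells with IL-10, IL-4 and IL-13 lay below that of M-CSF plates with thinning and above it without. With 1 plate left out at a time, IL-10 had 3 to 10 genes up, 0 to 2 down and 3 to 9 lists, and TGF-beta 185 to 254 down. IL-4 against IL-13 had 174 to 214 up and 245 to 328 down, and Zeb2 with IFN-gamma −0.79 to −0.43. Except where construction shows it, the cause was not tested.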

Other observations

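Across the 4 cytokines with 3 plates each, 32 genes fell with IL-4, IL-13, TGF-beta and IFN-gamma alike, a set looked at after the results were seen. Independent lists of these sizes would share 0.104. Unchanged groups simulated with redrawn M-CSF plates common to all contrasts shared 0. That 0 follows from simulating no change, since hardly any gene then passes. It does not measure what common controls add among changed genes. The 32 include Maf, Selenop, the iron exporter Slc40a1, the lipid transfer protein Pltp, the lysosomal protease Lgmn and the immediate early and NF-kB feedback genes Fos and Nfkbia. Fos, Ier3 and Zfp36, also among the 32, belong to the immediate early and heat shock list, which was set as a list of handling stress. Whether the M-CSF plates were handled differently was not tested. Genes that rose with all 4 numbered 7 (independent lists 0.136), among them Cd52, Eno1, Flt1 and Gpx1. The Eno1 call with TGF-beta ended without M-CSF replicate 3 (edgeR adjusted p = 0.0971) or TGF-beta replicate 3 (0.163). Part of these overlaps may come from the shared M-CSF plates, and 3 control plates do not allow a split.

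IL-4 and IFN-gamma both raised 219 genes and both lowered 281, where independent lists would share 76.0 and 65.8, and 110 genes passed in opposite directions (independent lists 143). Their log2 fold changes over 7098 genes had a correlation of 0.327 and a covariance of 0.399. Unchanged groups simulated with redrawn M-CSF plates common to both contrasts gave 0.589 and 0.0906. The observed correlation was the lower one while the covariance was higher by 0.308. In groups simulated without change, noise in the shared M-CSF plates alone sets the correlation. It is therefore no bound for changed groups, and the lower observed value does not make these cytokines less alike than chance.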
